A study of Mus musculus with 8 samples.

How the data were processed

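RNA was measured by sequencing in GFP-positive cells sorted from the mouse amygdala at embryonic day 16.5. The sorted population is the intercalated cells (ITCs), small clusters of GABAergic neurons that surround the basolateral amygdala. Per the labels' protocols, tissue from embryos of 1 genotype was pooled and dissociated before the sort, cDNA was amplified with a NuGEN Ovation kit, and Nextera XT libraries were sequenced on an Illumina HiSeq. Control pools came from Tshz1 GFP/+ embryos and knockout pools from Tshz1 GFP/RA embryos, with 4 libraries per genotype. The design text of the series speaks of triplicates, while the labels hold 4 samples per genotype, and all 8 were used. Each title begins with a prefix (NX, NY, QT or RM) that a control and a knockout library share, and the labels do not say what it marks.

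Per the submitters' processing notes, the authors used Trimmomatic 0.33, Bowtie2 and RSEM 1.2.22 with the mouse build mm10; the Bowtie2 version and the annotation release are not given in the sources used here. Per the file headers, each sample file holds RSEM expected counts and TPM per gene. Expected counts are estimated numbers of fragments that need not be whole, because RSEM shares a fragment that maps to several places among them. The deposited TPM values are scaled to gene length and to the total of each library, so they carry no depth. The deposited matrices of the whole series were compared with the sample files in 16 columns, and the largest difference was 0. The kit's protocol as named in the labels does not mark the strand, so fragments of a gene and of an antisense partner over its exons cannot be told apart. The amplified fragments carry no molecular identifiers, so floors given here cover counting error only.

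Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings, which left 14157 of 32543 genes. Composition factors were TMM, and the quasi-likelihood test (glmQLFit and glmQLFTest) compared knockout with control with genotype as the single term. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were taken from the quasi-likelihood F. CPM values are counts scaled to a common library total and by TMM, and means are given with the SD over 4 libraries. The level of Tshz1 was also compared by an exact two-sided permutation test of log2 CPM (prior count 2) over all 70 orders of the 8 libraries. Because each library is a pool of embryos, p-values measure the spread between pools. The labels do not say that the pools are independent litters.

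The 27 gene lists were written from general knowledge of the tissue, and the same holds for the rule for naming genes, the tests and most alternatives: these choices were made before the data were examined. Each list with at least 3 tested members was compared with the other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 25 lists tested. The hypothalamic and medial amygdala list had 0 tested members. The mitochondrially encoded list had none either, because no symbol began with mt-, and mitochondrial transcripts under other names were not looked for. An estimated correlation per list and fry were run as alternatives. Genes named in the report are Tshz1 itself, up to 8 called rises and 8 called falls with an average log2 CPM of at least 1 and groups that did not overlap, up to 4 called members of each list or else its tested member with the smallest p, and 8 genes fixed by name (Foxp2, Meis2, Pax6, Oprm1, Drd1, Prokr2, Tshz2 and Tshz3). A gene named outside this rule is said to be chosen after its values were seen, and some genes that the rule names are not reported here.

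Library totals ran from 5785549 to 14535810 expected counts, so 3 counts, taken as the floor of detection, corresponded to between 0.186 and 0.545 CPM. Alternatives changed the composition factors, the low-count filter, the threshold, the title prefix as a block, the libraries left out, the test (DESeq2 1.42.0, limma-voom, robust quasi-likelihood) and the unit (log2 of TPM plus 1 or plus 0.1 with limma-trend). The procedure was tested on simulated counts for the knockout against control comparison, with 50 genes changed at each size among 13398 tested. It recovered 18% of the genes changed 2-fold, 82% of those changed 4-fold and 100% of those changed 8-fold or 16-fold, and called 8 unchanged genes. The changed genes were drawn from those with an average log2 CPM above 3, and the simulated libraries shared no variation by prefix. These shares are therefore no bound for the real libraries. There Cyp26b1, at an average log2 CPM of 6.87, was 8.63-fold higher but not called (quasi-likelihood test, adjusted p = 0.126). Gene positions are from the GENCODE annotation of GRCm38, whose symbols matched 86.1% of the tested genes (12195 of 14157). The columns of the files were all assigned to a sample.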

Results

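Expression was measured by RNA sequencing in sorted amygdalar intercalated cells from mouse embryos at E16.5, in 4 control pools (Tshz1 GFP/+) and 4 knockout pools (Tshz1 GFP/RA). The comparison asks which transcripts of these neurons differ when Tshz1, a zinc finger transcription factor of the teashirt family, is disrupted. Control libraries held 14535810 (NX), 13690781 (NY), 12622908 (QT) and 5785549 (RM) expected counts. Knockout libraries held 13295631 (NX), 12095637 (NY), 6384499 (QT) and 7447874 (RM). Pearson correlations of log2 CPM across genes ran from 0.858 to 0.943 between libraries of 1 genotype and from 0.846 to 0.950 between genotypes, so libraries did not group by genotype as a whole. The first principal component held 33.7% of the variance and had the control NX library at one end (-94.2) and the knockout RM library at the other (61.0). Next to them lay the other library of the same prefix, knockout NX (-54.8) and control RM (46.4). The NY libraries lay close together (9.25 control, 9.59 knockout), and the QT libraries farther apart (-5.11 control, 27.9 knockout).

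Tshz1 transcript fell in the knockout from 381 ± 115 CPM to 79.1 ± 29.4 CPM (SD, n = 4 per genotype), a 4.81-fold lower level. Every knockout library lay below every control library, with control values of 492 (NX), 240.0 (NY), 457 (QT) and 337 CPM (RM) and knockout values of 121 (NX), 61.6 (NY), 78.1 (QT) and 55.9 CPM (RM). The log2 fold change was -2.27 (SE 0.30), with an adjusted p of 0.0388 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 libraries can give. The difference in log2 CPM was -2.13 among the 5 libraries with 12095637 counts or more and -2.35 among the other 3. Tshz1 lies on the minus strand of chromosome 18 from 84011627 to 84087706 (GRCm38) and is protein-coding. The labels do not give the part of the gene that the RA allele lacks, so the remaining counts cannot be assigned to an intact or an altered transcript. EGFP, the reporter carried by both genotypes and chosen after its values were seen, stood at 47.3 ± 16.8 CPM in control and 24.6 ± 12.8 CPM in knockout libraries (n = 4 each, exact permutation p = 0.114). Its log2 fold change was -0.94 (SE 0.37, unadjusted p = 0.026 in edgeR's quasi-likelihood test), and it did not pass over all genes. The reporter was lower in the knockout in 4 of 4 prefixes and fitted lower in 25 of 25 alternatives. The cause of its lower level was not tested.

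Besides Tshz1, 3 genes fell and 1 rose in the knockout. Tle4, a Groucho-family transcriptional corepressor, fell from 244 ± 73.7 to 65.6 ± 12.9 CPM (SD, n = 4 per genotype), a 3.72-fold lower level. Rgs8, a regulator of G protein signalling, fell from 203 ± 76.2 to 40.7 ± 16.1 CPM (4.998-fold lower). Tox, an HMG-box transcription factor, fell from 47.6 ± 4.31 to 17.9 ± 1.18 CPM (2.66-fold lower). Calcrl, the calcitonin receptor-like receptor that binds CGRP or adrenomedullin with its partner proteins, rose from 4.72 ± 2.31 to 128 ± 132 CPM, a 26.4-fold higher level with a wide spread: its knockout values were 323 (NX), 72.2 (NY), 85.4 (QT) and 32.9 CPM (RM). Without the knockout NX library the log2 fold change of Calcrl was 3.71 in place of 4.72. For each of these genes the 2 genotypes did not overlap, which by itself fixes the same direction in 4 of 4 prefixes.

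The log2 fold changes were -1.89 (SE 0.25) for Tle4, -2.32 (SE 0.34) for Rgs8, -1.41 (SE 0.21) for Tox and 4.72 (SE 0.68) for Calcrl. Adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0388 for Tle4 and 0.0482 for Rgs8, Tox and Calcrl. In GRCm38, Tle4 lies on the minus strand of chromosome 19 (14448150 to 14598051), Tox on the minus strand of chromosome 4 (6686353 to 6991557) and Calcrl on the minus strand of chromosome 2 (84330626 to 84425411). Rgs8 lies on the plus strand of chromosome 1 (153653025 to 153700323). Antisense models overlap exons of Rgs8 (Gm29529) and of Tox (Gm11802), and counts without strand cannot separate them from these genes. In all, 5 of 14157 tested genes passed (1 higher, 4 lower), while 512 had an unadjusted p under 0.05 (241 higher, 271 lower) where chance gives 708. The genotypes did not overlap for 366 genes, 2.59% of those tested against 2.86% by chance. The calls sat close to the threshold: no gene passed without the control NX, knockout NY, control QT, knockout QT or control RM library (with 328 to 716 genes at an unadjusted p under 0.05 in edgeR), and 1 passed without knockout RM (Calcrl), 4 without control NY and 5 without knockout NX, of which 3 and 2 were among the 5. DESeq2 called 39 genes including all 5, limma-voom called Tle4 and Tshz1, and edgeR called 0 without both the control NX and knockout QT libraries, which lay farthest out in the principal components. With the title prefix as a replicate block, edgeR called 28 genes including all 5.

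**Figure D1:**
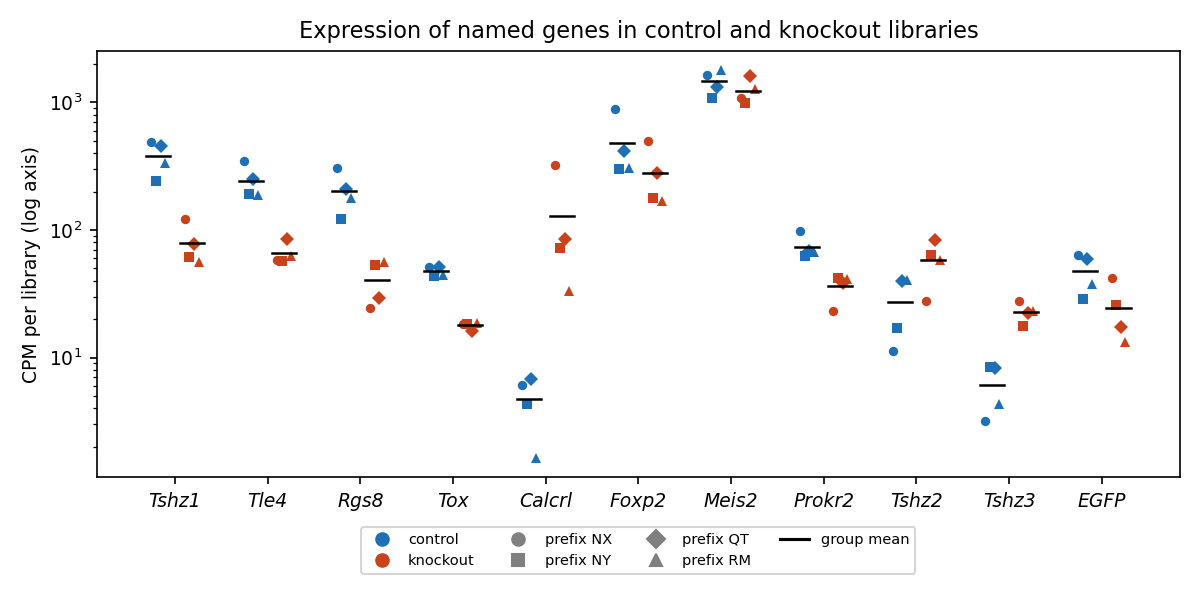
CPM (log axis) of 10 named genes and the EGFP reporter in each control and knockout library, with symbols for the title prefix and bars for the group mean. Tshz1, Tle4, Rgs8 and Tox lie lower and Calcrl lies higher in all 4 knockout libraries than in any control library, while the genotypes overlap for Foxp2, Meis2, Tshz2 and EGFP.

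Tshz1 was the single one of 12 tested members of the intercalated cell list to pass over all genes, and Tshz1, Drd1 and Erbb4 fell when adjusted over the list alone. That adjustment counts the disrupted gene itself, whose small p eases the threshold for the other members. Adjusted over the list, edgeR's p was 0.0441 for Erbb4 and 0.0499 for Drd1, from unadjusted p of 0.00735 and 0.0125. A list without Tshz1 was not tested, so neither call is shown apart from the disrupted gene. Drd1, a dopamine receptor, went from 8.86 ± 3.82 to 2.99 ± 1.74 CPM (log2 fold change -1.57, SE 0.54). The genotypes overlapped for Drd1, which was lower in 3 of 4 prefixes, with QT at 4.51 CPM in control and 5.18 CPM in knockout, and its log2 fold change was -2.18 without both QT libraries. Erbb4, a neuregulin receptor named after its values were seen, went from 129 ± 24.3 to 74.4 ± 23.3 CPM (-0.79, SE 0.25; n = 4 per genotype). Foxp2, a forkhead transcription factor typical of these neurons, had 478 ± 278 CPM in control and 281 ± 153 CPM in knockout libraries (-0.77, SE 0.41), lower in 4 of 4 prefixes but not past the test over all genes or over the list. Meis2 (1458 ± 315 against 1236 ± 265 CPM, log2 fold change -0.24, SE 0.24) did not pass. Pax6 (-0.04, SE 0.34) and Oprm1, the mu opioid receptor (-0.35, SE 0.76), did not pass either, and the sign of both depended on the libraries used. Ipcef1 overlaps exons of Oprm1 on the other strand. The list as a whole had 8 of 12 members fitted lower and an adjusted p of 0.0959 by camera, and 0.870 with an estimated correlation. It passed as lower without the control NY (0.0468), knockout QT (0.0153) or knockout RM library (0.0418) and without both QT libraries (0.00869), all adjusted p by camera. These list tests also count the disrupted gene, and camera was not run without it. The median log2 fold change of the list was -0.14, against -2.27 for Tshz1.

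The teashirt family moved in both directions. Tshz3 went from 6.06 ± 2.70 to 22.8 ± 4.15 CPM (log2 fold change 1.90, SE 0.37) and Tshz2 from 27.2 ± 15.1 to 58.4 ± 22.9 CPM (1.11, SE 0.42), each higher in 4 of 4 prefixes (n = 4 per genotype). Neither passed over all genes, with adjusted p of 0.161 for Tshz3 and 1.00 for Tshz2 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Adjusted over the list alone, all 3 members passed, with Tshz2 and Tshz3 higher and Tshz1 lower. Expected counts of Tshz1 and Tshz3 were exactly whole in 8 of 8 libraries and those of Tshz2 in 7 of 8, and a fragment that RSEM shares between places usually leaves a fraction. The antisense models A630075F10Rik and Gm26883 overlap exons of Tshz2. The family's list test had an adjusted p of 0.562 by camera.

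In the dorsal LGE and olfactory bulb lineage list, Tshz1, Prokr2 and Eya2 fell when adjusted over the list alone, and only Tshz1 of 12 tested members did so over all genes. Prokr2, a prokineticin receptor, went from 74.0 ± 15.98 to 36.3 ± 8.80 CPM (log2 fold change -1.03, SE 0.25; n = 4 per genotype) with no overlap between genotypes, and its adjusted p over all genes was 0.474 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Eya2, a transcriptional coactivator and phosphatase chosen after its values were seen, went from 8.22 ± 4.09 to 0.178 ± 0.257 CPM, with 230, 96, 79 and 30 counts in the control libraries against 8, 0, 0 and 1 in the knockout libraries (NX, NY, QT and RM). The list had 8 of 12 members fitted lower, with an adjusted p of 0.0959 by camera (0.0475, lower, without both NY libraries), and 0.870 with an estimated correlation and all libraries. These tests count Tshz1 itself, and the median log2 fold change of the list was -0.03 against a mean of -0.60. In fry's mixed test, which asks whether members change in either direction, this list (adjusted p = 0.000171) and the intercalated cell list (0.00129) passed, and both hold Tshz1.

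None of 14 tested members of the pan-GABAergic list passed, and the list mean was 7.29 ± 0.13 log2 CPM in control and 7.23 ± 0.18 in knockout libraries (n = 4 each). Within prefixes the knockout mean was lower in NX (7.02 against 7.40) and QT (7.14 against 7.40). It was higher in NY (7.32 against 7.16) and RM (7.43 against 7.20). A lack of calls does not show that GABAergic identity was unchanged. The member of this list with the smallest p was Slc32a1, the vesicular GABA transporter, at 64.0 ± 10.6 against 43.4 ± 6.58 CPM. It was lower in 4 of 4 prefixes and not past the test, and Gm14205 overlaps its exons on the other strand. None of 21 striatal projection neuron genes passed, with Adora2a, an adenosine receptor, at 14.6 ± 6.81 against 34.3 ± 13.6 CPM. In the MGE and CGE interneuron list, Adarb2 (155 ± 58.9 against 81.8 ± 16.4 CPM, chosen after its values were seen) fell when adjusted over the list alone, and 0 of 17 passed over all genes. In edgeR's quasi-likelihood test 3 striatal genes were higher and 2 lower at an unadjusted p under 0.05, and 1 MGE and CGE gene was higher and 2 were lower.

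Among 50 axon guidance and migration genes, 2 rose and 2 fell when adjusted over the list alone, and 0 passed over all genes. Dcc, a netrin receptor, went from 249 ± 12.1 to 97.3 ± 34.9 CPM (log2 fold change -1.36, SE 0.25) and Prokr2 was the other one lower. Efna5, an ephrin, went from 9.95 ± 2.46 to 30.0 ± 14.4 CPM and Slit3, a ligand of Robo receptors, from 28.8 ± 12.2 to 70.8 ± 15.2 CPM, both chosen after their values were seen. In the retinoid, Wnt, BMP and Notch list, Cyp26b1, which degrades retinoic acid, rose adjusted over the list alone, from 24.1 ± 5.38 to 209 ± 201 CPM, with the knockout NX library at 499 CPM, and its log2 fold change was 3.11 with all libraries and 2.21 without that one. Wnt5a, chosen after its values were seen, fell in the same adjustment from 57.2 ± 30.2 to 17.996 ± 6.50 CPM, and Gm2670 overlaps its exons on the other strand. In the apoptosis and p53 list, Bcl2l11, which encodes the pro-apoptotic protein BIM, fell adjusted over the list alone, from 48.8 ± 9.30 to 21.0 ± 6.43 CPM, and the other 17 tested members did not pass. Over all genes, adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.126 for Dcc and Cyp26b1 and 0.333 for Bcl2l11. Dcc, Cyp26b1, Bcl2l11 and Wnt5a were called over all genes by edgeR with the prefix as a block and by DESeq2 without it. Efna5 was called by DESeq2 alone of these, and Prokr2 and Slit3 by neither.

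As groups, 3 of 25 lists passed the camera test with the preset correlation, and none of the 3 passed with an estimated one. Cell cycle genes were fitted higher in the knockout for 24 of 26 members, with a median log2 fold change of 0.88 and an adjusted p of 3.68e-05 by camera, but 0 members passed singly in the fit without the prefix; adjusted p = 0.899 with an estimated correlation. Ccnb1, which drives entry into mitosis, stood at 20.4 ± 9.13 against 49.1 ± 29.3 CPM (n = 4 per genotype). Library means of the cell cycle list were 4.13 ± 0.96 log2 CPM in control and 4.84 ± 1.16 in knockout libraries, and the list lost its call without the control NX library (adjusted p = 0.107 by camera) and without both control NX and knockout QT (0.567). It kept its call in 11 of 12 fits with a library or prefix left out, also without both NX libraries (1.89e-18), and with the prefix as a block (9.11e-14). These values use the preset correlation. With the block and an estimated correlation the adjusted p by camera was 0.615. Cytoplasmic ribosomal protein genes were fitted lower for 74 of 84 members (median -0.21, adjusted p 0.00771 by camera; adjusted p = 0.919 with an estimated correlation), and Rpl36al, with the smallest p, had 69.98 ± 13.8 against 51.2 ± 18.6 CPM, which includes any reads of Gm49383 over the same exons. Glycolysis and hypoxia genes were fitted lower for 15 of 19 members (median -0.29, adjusted p 0.0405 by camera; adjusted p = 0.870 with an estimated correlation), with Vegfa at 30.1 ± 6.64 against 16.9 ± 6.04 CPM. The ribosomal list lost its call without the control NX (adjusted p = 0.536), control NY (0.756), knockout QT (0.704, other direction) or knockout RM library (0.333) and without both libraries of NX (0.355) or QT (0.102), and passed in the other direction without both control NX and knockout QT (0.00940). The glycolysis list lost its call without the control NY (0.209), control QT (0.0659), knockout QT (0.0846) or knockout RM library (0.155), and without both libraries of NY (0.159), QT (0.102) or RM (0.0758). It also lost it without composition factors (0.0713) and with thinned libraries (0.0585), all adjusted p by camera.

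**Figure D2:**
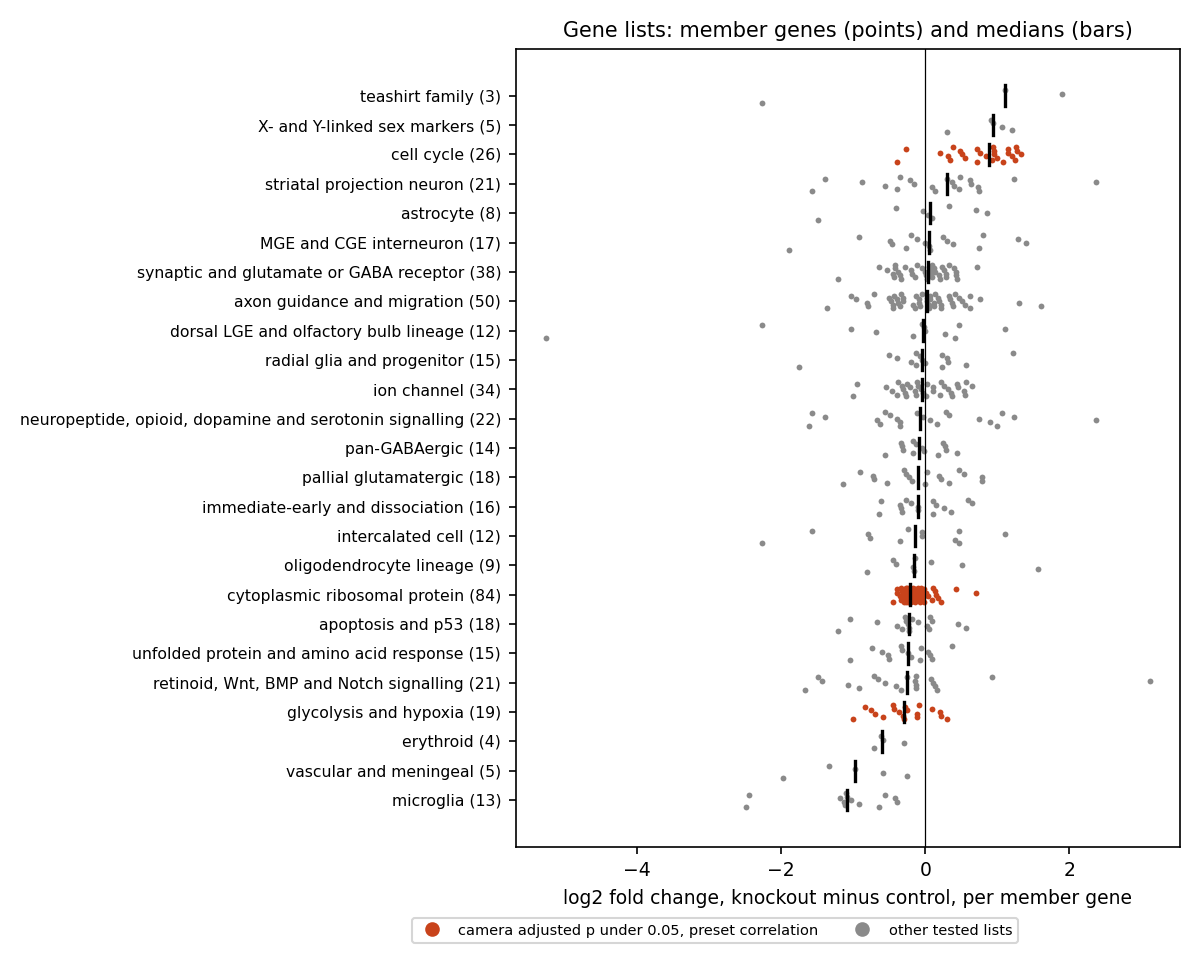
Log2 fold change (knockout minus control) of each tested member gene (points) and the list median (black bar) for the 25 lists, with the number of tested members in brackets. Cell cycle members sit mostly to the right of 0 (median 0.88), and ribosomal protein and glycolysis members mostly to the left (medians -0.21 and -0.29).

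With all 8 libraries, lists of cell types other than intercalated cells did not pass, but some did with a library left out. All 13 tested microglia genes were fitted lower in the knockout (median -1.08, adjusted p 0.0959 by camera; Ptprc 3.02 ± 2.52 against 0.536 ± 0.535 CPM), and the same was true of 5 of 5 vascular and meningeal genes (Cdh5 2.04 ± 2.61 against 0.554 ± 0.653 CPM). The Cdh5 value rests largely on the control NY library at 5.85 CPM: its log2 fold change was -1.97 with all libraries and -0.47 without that one. Microglia list means were 1.87 ± 2.07 log2 CPM in control and 1.16 ± 1.01 in knockout libraries. Without the control NX library both lists passed as lower, with an adjusted p by camera of 3.16e-10 for microglia and 0.0101 for vascular and meningeal genes, against 0.919 and 0.940 with an estimated correlation and all libraries. The microglia list also passed as lower without knockout NY (0.0288), knockout RM (0.0418) or both NX libraries (1.36e-06) and with the level of Y-linked genes as a covariate (6.14e-05), by camera. In the pallial glutamatergic list, 8 of 18 genes were fitted higher, with Neurod6 at 43.0 ± 29.1 against 74.5 ± 38.7 CPM. That list passed as higher without control NY (adjusted p 0.0196 by camera) or control QT (0.000726) and as lower without control NX (0.00877), against 0.919 with an estimated correlation and all libraries. In the radial glia and progenitor list, 6 of 15 were fitted higher, with Sox9 at 24.8 ± 15.4 against 57.7 ± 13.2 CPM. In the oligodendrocyte list, 3 of 9 members were fitted higher. Of 8 astrocyte genes, 5 were fitted higher (Slc4a4 29.1 ± 4.77 against 47.6 ± 12.3 CPM), and 4 of 4 erythroid genes were fitted lower, with Hbb-bs at 47.8 ± 83.9 against 29.1 ± 40.8 CPM (log2 fold change -0.71, and 2.32 without the control NY library). The control NX library stood apart: its pallial list mean was 0.80 log2 CPM against 3.38 to 4.51 in the other 7 libraries, and its cell cycle mean was 2.76, the lowest of the 8.

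The remaining lists did not pass either with all 8 libraries. Fitted members were higher for 21 of 38 synaptic and receptor genes (Syt1 141 ± 46.8 against 97.2 ± 21.5 CPM), 16 of 34 ion channel genes (Cacna2d3 33.9 ± 9.48 against 16.9 ± 6.25 CPM) and 10 of 22 neuropeptide, opioid, dopamine and serotonin genes. They were higher for 7 of 16 immediate-early and dissociation genes (Fosl2 14.3 ± 7.36 against 9.13 ± 3.75 CPM) and 4 of 15 unfolded protein and amino acid response genes (Psat1 82.7 ± 20.2 against 54.7 ± 22.4 CPM). Over the 22 lists without a call, adjusted p ran from 0.0959 to 0.906 by camera. Median, mean and camera direction differed in sign for the pallial, radial glia, oligodendrocyte, erythroid, axon guidance, synaptic and neuropeptide lists. Sex-linked genes differed widely between pools of either genotype. The 4 Y-linked genes together stood at 1.92 (NX), 74.5 (NY), 1.07 (QT) and 109 CPM (RM) in control and at 109 (NX), 171 (NY), 4.26 (QT) and 77.7 CPM (RM) in knockout libraries. In the control NX, control QT and knockout QT libraries Ddx3y and Eif2s3y had 0 counts, and the low sums rest on Kdm5d, with 30, 14 and 28 counts. Xist was at 9.11 CPM in the knockout NY library and between 1643 and 10065 CPM in the other libraries. The sex marker list, with Kdm5d at 23.6 ± 27.0 against 44.5 ± 29.1 CPM (log2 fold change 0.94, and 1.83 without the control RM library), had an adjusted p of 0.242 by camera, and passed as higher without the knockout QT library (0.00899), against 0.899 with an estimated correlation and all libraries.

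**Figure D3:**
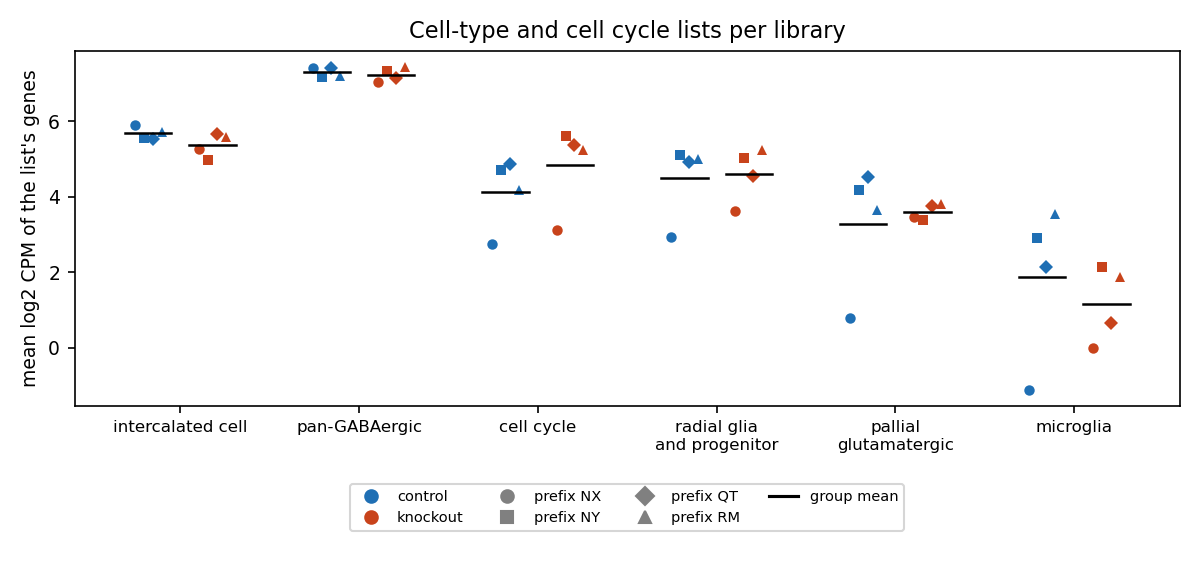
Mean log2 CPM of the genes of 6 lists in each control and knockout library, with symbols for the title prefix and bars for the group mean. The pan-GABAergic list lies between 7.02 and 7.43 in all 8 libraries, while the pallial and microglia lists drop to 0.80 and -1.10 in the control NX library.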

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

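Tests of library totals as a source of few small p-values, all tests of the cell cycle pattern and both tests of the control NX library were chosen only after the result was seen. Of 120 groups of 4 libraries examined, 10 held a library far from the other 3 by Dixon's criterion of the gap over the range, and chance gives about 1 in 20. Tox stood at 4.03 log2 CPM in the knockout QT library against 4.21 to 4.23 in the other knockout libraries, a small distance within a very tight group. Ccnb1 was at 2.53 in knockout NX against 5.86 to 6.06, and Prokr2 at 4.55 in knockout NX against 5.28 to 5.40. Psat1 was at 6.82 in control QT against 6.17 to 6.20, and Rpl36al at 6.31 in knockout NY against 5.36 to 5.44. Kdm5d, on the Y chromosome, was at 2.15 in knockout QT against 5.62 to 6.21. Among list means, the knockout NX library was low for cell cycle genes (3.11 against 5.24 to 5.62 log2 CPM). The control NX library was low for MGE and CGE interneuron genes (2.82 against 4.39 to 4.63), radial glia and progenitor genes (2.94 against 4.91 to 5.12) and axon guidance and migration genes (5.26 against 5.98 to 6.10).

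The control NX library was the lowest of the 8 libraries in 7 of 8 lists of other cell types (pallial, MGE and CGE, radial glia, oligodendrocyte, astrocyte, microglia and vascular, with erythroid the exception), with Tbr1 at 8.37 CPM against 41.2 to 175 elsewhere, Fabp7 at 20.5 against 72.6 to 652 and Pdgfra at 0.062 against 1.63 to 28.9, genes chosen after their values were seen. Low depth is argued against, since its total ranked 1 of 8 with 14535810 counts. Fewer cells of other types in that pool, left after a cleaner sort for GFP, stay open as a hypothesis. Some genes of these lists went the other way there, with Adarb2 at 236 CPM against 67.0 to 152 and Acsl3 at 68.0 against 51.1 to 66.1 (both chosen after their values were seen), and both may also be expressed in the sorted neurons. A difference in the embryos of the control NX pool was not tested. The knockout NX library was next lowest for the MGE and CGE (3.76 log2 CPM), radial glia (3.62), oligodendrocyte (0.50), microglia (-0.02) and vascular lists (-0.16). It was not so for the pallial and astrocyte lists. Part of the pattern was therefore shared within the NX prefix.

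Cell cycle genes were higher in knockout libraries within each prefix, by 0.35 (NX), 0.90 (NY), 0.50 (QT) and 1.07 (RM) log2 CPM, a mean difference of 0.71. Unequal totals are argued against, since the difference was still 0.71 with all libraries thinned to 5785549 counts. Pool differences unrelated to genotype stay open: the 2 genotypes overlapped, with an exact two-sided permutation p of 0.4 over 70 orders, a test that takes no account of the prefix. A larger share of radial glia in knockout pools was not told apart from a genotype effect by a fit without the prefix, where the difference was 0.71 (SE 0.76) before the radial glia list mean entered as a covariate and 0.59 (SE 0.38) after; the 4 differences within prefixes have an SE of 0.17, and those of the radial glia list were 0.68 (NX), -0.09 (NY), -0.37 (QT) and 0.23 (RM). A genotype effect on dividing cells in the sort therefore stays a hypothesis that these pools do not settle.

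Fewer genes than chance gives had a small p between genotypes: 512, or 3.62%, at an unadjusted p under 0.05 in edgeR's quasi-likelihood test. Unequal totals are argued against, since thinning left the share at 3.76%. A source of variation shared by libraries of the same title prefix is consistent with the data, because a split that kept prefixes together (NX and NY against QT and RM) gave 1893 such genes. The other 2 such splits gave 1209 and 589, splits that kept 2 of the 4 prefixes together gave from 222 to 1730, and those that parted all 4 gave from 115 to 442 beside the 512 between genotypes. With the prefix as a replicate block, 1013 genes had an unadjusted p under 0.05 between genotypes in edgeR, above the 708 that chance gives. What the prefix marks is not in the labels.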

How the results depend on the processing

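The fits without both the control NX and knockout QT libraries, without features above 1 percent of a library, with thinned libraries and with the level of Y-linked genes as a covariate, and the blocked list test with an estimated correlation, were chosen only after the result was seen. Tshz1, Tle4, Rgs8, Tox and Calcrl kept their direction in 25 of 25 alternatives each and were called in 13, 10, 10, 5 and 12 of them; the cause of lost calls was not tested, though leaving libraries out also leaves fewer samples. Against 5 genes, edgeR called 9 (1 higher, 8 lower) without composition factors, 19 without a low-count filter, 2 with robust quasi-likelihood, 11 at an adjusted p under 0.1, 2 without features above 1 percent, 0 with the Y-linked covariate (521 at an unadjusted p under 0.05) and 0 without control NX and knockout QT (353 at that p). DESeq2 called 39, limma-voom 2 and log2(TPM + 1) with limma-trend 10; leaving out libraries or prefixes gave 0 to 5. Tshz1 was not called at log2(TPM + 0.1) (-2.37, limma-trend adjusted p = 0.0815), without control NX and knockout QT (-2.11, edgeR adjusted p = 0.385) or with the Y-linked covariate (-2.07, edgeR adjusted p = 0.222), within a range of 2.36e-09 (DESeq2) to 0.618; without 1 library or prefix it ranged from -2.55 to -2.12 and was called in 3 of 12. Uncalled genes changed sign: Pax6 to 0.00108 with limma-voom, 0.0916 and 0.0990 with TPM, 0.0693 without control NX and knockout QT and 0.27 with the Y-linked covariate (-0.29 to 0.16 with libraries left out), Hbb-bs to 0.74 with limma-voom (-2.41 to 2.32) and Oprm1 (-0.95 to 0.28). For lists, an estimated correlation, fry's directional test and the blocked test with an estimated correlation called 0 of 25, and 6 (2 higher, 4 lower) were called without control NX and knockout QT; there the pallial list, directed higher and uncalled with all libraries, was called lower (camera adjusted p = 0.000471) and the ribosomal list higher (0.00940). The glycolysis list kept its call in 12 of 24 alternatives, and the microglia, vascular and intercalated cell lists, uncalled with all libraries, were called lower in 7, 3 and 4. The intercalated cell list counts Tshz1 itself. With libraries left out the pallial list, where called, ranged from 0.000726 to 0.0196 (lower without control NX, 0.00877), and the ribosomal list from 7.74e-16 to 0.756 (higher without knockout QT, 0.704). The rule used took the title prefixes to pair the libraries only if deviations from the group means correlated by over 0.1 in every prefix. They correlated by 0.38 (NX), 0.30 (NY), 0.07 (QT) and 0.45 (RM), so the rule was not met, through QT alone. Both libraries correlated best with their own prefix in 3 of 4. With the prefix as a replicate block edgeR called 28 genes (11 higher, 17 lower, with 1013 at an unadjusted p under 0.05), including all 5 and Ccna2 of the cell cycle list. Ccna2 was chosen after its values were seen (log2 fold change 1.28, SE 0.21, edgeR adjusted p = 0.0432). DESeq2 with the block called 170 (106 higher, 64 lower, with 1233 at that p). Camera with the block and the preset correlation called 4 lists, the 3 called without it and the microglia list as lower (adjusted p = 0.0189). Chance could not be excluded by splits that ignore the prefix: 3 of the 35 splits of the 8 libraries called at least 5 genes, the real one among them. The highest other, with NX and NY against QT and RM, called 49, which points to a structure among the libraries. The third kept both NX and both RM libraries together and called 6, and the remaining 32 called 0 or 1. Among the splits that parted all 4 prefixes, as the genotypes do, the real one called 5 genes and every other called 0. Those splits are too few to give a share under 0.05, so they do not settle the question either. At least 3 lists were called in 32 of 35 splits, up to 14 against 3. Low totals limit genes near the floor: Nmbr had 10 counts in the control RM library.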

Other observations

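The genes and features in this part were singled out only after the result was seen, with no tests added for them. At an adjusted p between 0.05 and 0.1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6 further genes stood out, 5 lower and 1 higher, each with no overlap between genotypes. Casz1, a zinc finger transcription factor, stood at 40.3 ± 9.83 CPM in control and 6.67 ± 3.26 CPM in knockout libraries (SD, n = 4 per genotype), with the model Gm13205 on the other strand over its exons. St3gal1, a sialyltransferase, stood at 83.8 ± 35.1 against 23.1 ± 3.36 CPM, and Ajap1, an adherens junction protein gene, at 25.2 ± 12.7 against 4.94 ± 0.522 CPM. Pde1c, a cyclic nucleotide phosphodiesterase, was higher, at 25.1 ± 5.80 against 74.3 ± 16.53 CPM. Nmbr, the neuromedin B receptor, had 150 counts over the control libraries and 0 over the knockout libraries, at least 40.8-fold lower against a floor of 3 counts over the group, with B230364G03Rik on the other strand. Eya2 was close to absence in the knockout as well, with at most 8 counts in a library.

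Several further genes had genotypes that did not overlap and an adjusted p above 0.1 in the same test. Lower in the knockout were Lypd1 (57.5 ± 25.5 against 9.53 ± 6.71 CPM), Plekhh2 (81.6 ± 44.3 against 15.2 ± 6.87 CPM), Zfp536 (82.3 ± 26.3 against 32.5 ± 4.62 CPM), Grm4, a metabotropic glutamate receptor (32.7 ± 9.74 against 11.2 ± 3.97 CPM), and Pcp4 (46.5 ± 20.0 against 10.04 ± 7.09 CPM). Exons of Pcp4 overlap those of Igsf5 on the same strand, so their counts are uncertain. Higher were Rasgef1b (31.9 ± 12.4 against 101 ± 30.0 CPM), Dact1 (77.1 ± 23.7 against 200.2 ± 54.2 CPM), Lmo3 (48.4 ± 14.2 against 105 ± 24.1 CPM) and Nwd2 (1.14 ± 1.06 against 17.5 ± 13.3 CPM). Genes on the other strand overlap exons of Lypd1 (Gpr39), Plekhh2 (AC132353.1), Dact1 (4930474H06Rik) and Nwd2 (Gm9954). The knockout NX library held Nwd2 at 36.2 CPM, and the log2 fold change of Nwd2 was 4.07 with all libraries and from 2.97 to 4.72 with libraries left out. Bmf, which like Bcl2l11 encodes a BH3-only pro-apoptotic protein, was at 18.4 ± 5.22 against 4.29 ± 1.65 CPM. All of these genes were among the 39 that DESeq2 called.

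A few features took much of the counts in every library. The model GU332589 took between 8.73% (knockout NX) and 18.4% (knockout RM) of all counts, and the ribosomal precursor Rn45s between 0.718% (knockout QT) and 7.99% (knockout NY). The 10 most abundant features together took from 20.7% (knockout NX) to 44.5% (knockout RM).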
